A study of Mus musculus with 235 samples.

How the data were processed

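Liver RNA of female mice from 31 inbred strains was measured on Affymetrix mouse expression arrays with 3' in vitro transcription labelling, 1 array per animal. The 235 arrays comprised 124 from animals given vehicle and 111 from animals given isoniazid. The deposited values are log2 expression values per probe set, made by the authors with the RMA method in Affymetrix Power Tools, per the submitters' processing notes, and tool versions are not given in the sources used here. RMA subtracts background, equalises the distributions of the arrays and summarises the probes of each set on the log2 scale, so a shift common to all genes would be removed, and low values are compressed. The file held 44721 probe sets. Values ran from 1.15 to 14.65. Array medians ran from 3.96 to 4.21. Arrays give no counts, and their number limits the precision. Probes were designed on a reference sequence, so a sequence variant of a strain can lower the signal of a probe set in all animals of that strain.

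Probe sets were named through the array annotation supplied with the values. It gave 1 gene symbol for 34717 probe sets and several for 872, listed none for 9072, and 60 were controls. Of the 34717 named probe sets, 34514 were matched through their Entrez numbers to a mouse gene table of assembly GRCm38.p6, used for names only, and 0 symbols changed. Genes were named only from probe sets with 1 symbol, which left 18146 genes. Where a gene had more than 1 probe set (8949 genes), the probe set with the highest mean over all arrays was used. No filter on dim genes was applied in the main comparisons.

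The strain was the replicate in all comparisons over strains, since the steatosis code of the submitters is a property of the strain. For each gene and strain the mean of the vehicle animals was subtracted from the mean of the isoniazid animals. The 31 differences were tested with limma (lmFit and eBayes), over all strains, within each status group and between groups. The vehicle means were tested between status groups in the same way. Effects within each strain, the interaction of strain and treatment, and strain differences among vehicle animals were tested with limma in a fit of the 62 groups with animals as replicates, which has 173 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over the 18146 genes, and an adjusted p under 0.05 counted as a call. All limma p-values are two-sided. Intervals are 95% intervals of the difference over strains.

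The 37 gene lists of pathways, regulators and cell type markers were tested over strains with camera from limma at its preset correlation between genes of 0.01, with the correlation estimated from the data and fry as alternatives. Of 624 list entries, 562 were found among the genes, and the others were not analysed here. Some lists share members, such as Got1 and Alas1. Named genes followed a rule. Over the 31 strains these are the 12 highest and 12 lowest mean changes among genes that passed and changed the same way in at least 25 strains. Between strain groups the rule took up to 10 genes each way, or the 5 smallest p-values where fewer than 5 passed. From each list it took up to 4 members with the largest t, from each F test the 5 largest F, and in all cases it took a fixed set of lipid, drug metabolism and heme genes.

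Arrays were checked before use. No 2 arrays were identical, and the 337 pairs of arrays in the same group had Pearson r from 0.955 to 0.995 across genes (median 0.990). Of the 235 arrays, 234 correlated best with the mean of the other arrays of their own strain, among the means of all strains. This used the 2000 genes that varied most between strain means, which were chosen with the checked array included. The arrays had been scanned on 10 dates with 22 to 24 arrays each, and strains and treatments were mixed over the dates. A set of 21 arrays had a narrower spread of log2 values, with an SD of 2.10 to 2.20, below a gap in the sorted SDs, while the other arrays had SDs of 2.23 to 2.35. They were kept, and each count was recomputed without them, an alternative chosen after seeing the data. Single comparisons of 1 value were tested by two-sided permutation tests with 100000 resamples.

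The gene lists, the named-gene rule and the other alternatives were fixed before the data were examined. The alternatives were animals as replicates, scan date as a term, centring each array on its median, the mean of a gene's probe sets, leaving out genes below the 40th percentile of mean level (10888 genes left), weights by the number of animals, eBayes with trend and robust settings, each animal number and each strain left out in turn, only the 22 strains without deaths, the animal number as a block, and a threshold that also asked for a 1.5-fold change. For gene lists only the correlation, fry, scan date, the block and left-out strains were fixed in this way, and the other settings were applied to them after the data were seen. A list of proteasome genes and a measure of response size were also added after the data were seen. Leaving out an animal number can leave a group with 1 array, which is then assumed to vary like the other groups.

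The tests were tested on simulated arrays with the spreads of the real genes, in which 200 of 18146 genes were changed. For the effect over 31 strains, 96.0% of genes changed by 0.3 log2 and 99.0% of those changed by 0.5 were recovered. For the difference of effects by steatosis, recovery was 52.0% at 0.3 and 93.5% at 0.5, and for vehicle levels by steatosis 62.5% and 89.5%. Between 2.34% and 9.22% of the calls in these simulations were unchanged genes. For the interaction, with 200 genes changed by 1 log2 in 1 strain, recovery was 40.5%, and for the effect within that strain 90.0%. Simulated genes were independent, which real genes are not. The changed genes were drawn at random from all genes, dim ones included. Recovery can therefore be lower for genes whose effects vary widely between strains, such as Scd1. The analysis used R 4.3.3 with the packages limma (3.58.1) and data.table (1.17.8), and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.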

Results

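Gene expression was measured in the left liver lobe of female mice of 31 inbred strains, aged 8 to 10 weeks. The mice received isoniazid, an antibiotic used against tuberculosis that can injure the liver, or sterile water as vehicle, by oral gavage once a day for 3 days. The isoniazid dose was 100 mg/kg, and tissue was taken 24 h after the last dose. The arrays comprised 124 from vehicle animals, 4 per strain, and 111 from isoniazid animals. In 22 strains 4 isoniazid animals were measured, in 5 strains 3, and in 4 strains 2, because 13 isoniazid animals had died in 9 strains. The submitters coded 13 strains as showing steatosis, the accumulation of fat in liver cells, under isoniazid, and the other 18 as not. Of the 9 strains with deaths, 1 was a steatosis strain. Array medians lay between 3.96 and 4.21 log2 units. On 21 arrays, 10 of isoniazid and 11 of vehicle animals, the spread of the log2 values was narrower than on all others, and these arrays were retained.

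The first comparison asked what isoniazid changed in the liver across strains, with the strain as the replicate. The largest fall was that of Scd1, the desaturase that makes monounsaturated fatty acids, from 12.45 ± 0.73 to 10.96 ± 0.97 log2 units (mean ± SD, n = 31 strains), which is 2.82-fold lower. Csad, an enzyme of taurine synthesis, fell 2.62-fold, and Acot1 and Acot2, which release fatty acids from coenzyme A, fell 2.25-fold and 2.14-fold. The largest rise was that of Cidec, a lipid droplet protein, from 5.41 ± 1.09 to 6.40 ± 1.38 log2 units (1.99-fold). The apolipoprotein genes Apoa4 and Apoc2 rose 1.89-fold and 1.53-fold, and Alas1, the first enzyme of heme synthesis, rose 1.74-fold.

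By limma, 3636 of 18146 genes changed over the 31 strains, 1848 higher and 1788 lower. Most changes were small, and 54 genes, 17 higher and 37 lower, also changed at least 1.5-fold. Acot1, Acot2 and Dleu2, a long non-coding RNA, were lower in all 31 strains. Stap1 and Apoc2 were higher in all 31. Csad was lower in 30 strains by a mean of -1.39 (SE 0.11, adjusted p = 1.22e-11). Scd1 was lower in 30 strains by -1.50 (SE 0.16, adjusted p = 1.2e-08), and SWR/J was the exception at 0.67. Cidec was higher in 27 strains (log2 change 0.99, SE 0.14, adjusted p = 1.77e-06), with 3.13 in NZW/LacJ. Apoc2 had a log2 change of 0.61 (SE 0.05, adjusted p = 2.55e-11). Alas1 was higher in 28 strains by 0.80 (SE 0.09, adjusted p = 3.63e-08).

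The other genes named as rising were Pgm3 (log2 change 0.90), an enzyme of hexosamine synthesis, Cgref1 (0.89), the cytochrome P450 gene Cyp2b10 (0.87), 2010003K11Rik (0.83), Tkfc (0.67), which phosphorylates glyceraldehyde from fructose, Got1 (0.64), the cytosolic aspartate aminotransferase, and 1810055G02Rik (0.60). Their adjusted p-values lay between 6.91e-09 for Pgm3 and Tkfc and 5.68e-05 for Cyp2b10. The other genes named as falling were Serpina4-ps1 (-1.41), Dnase2a (-1.23), a lysosomal nuclease, 9030619P08Rik (-1.17), Dio1 (-0.85), a thyroid hormone deiodinase, the early response gene Fos (-0.84), Rsad2 (-0.78), an interferon-induced gene, and D630004K10Rik (-0.77). Among these the highest adjusted p was 2e-05, for Fos. A second probe set of Acot2 gave -0.13, and the 3 probe sets of Dleu2 ran from -0.94 to -0.01. All 24 genes had the same sign within each of the 10 scan dates, as had 1785 of the 3636 genes. The 24 and the 3636 genes were chosen from the same arrays. Effects within a date had Pearson r of 0.51 to 0.83 across genes with the pooled effects. The pooled effects include the arrays of that date, which raises r by construction. With scan date as a term 3768 genes passed. Psat1, an enzyme of serine synthesis, had a mean of 0.93 but was higher in 20 strains, fewer than the 25 asked for here.

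Genes of lipid metabolism did not move as 1 group. Of 19 genes of fatty acid synthesis, 6 rose and 4 fell. Elovl6 and Elovl5, which lengthen fatty acids, rose by 0.58 and 0.32, and Acaca, which makes malonyl-CoA, rose by 0.26, while Scd1 fell. Fasn, the fatty acid synthase, rose by 0.27 (adjusted p = 0.00662, 24 strains). Of 29 targets of PPAR alpha and genes of fatty acid oxidation, 4 rose and 9 fell, Acot1, Acot2 and Vnn1 (-0.64) among those that fell. Cpt1a, the gate of mitochondrial fatty acid uptake, rose by 0.24 (adjusted p = 5.74e-05, 29 strains). Of 24 genes of lipid droplets and triglyceride turnover, 6 rose and 3 fell. Cideb rose by 0.30, whereas Plin4 (-0.57) and Gpat3 (-0.30) fell. Of 16 genes of lipoprotein assembly, 5 rose and 3 fell, with Apoa5 at 0.17 and Pltp at -0.31. None of these lists passed camera, with adjusted p of 0.0765, 0.0619, 0.169 and 0.155 in that order. Adjusted over the list alone, 7 rose and 4 fell, 4 and 10, 7 and 3, and 6 and 5. Plin2, the main lipid droplet coat protein, did not pass (0.19, adjusted p = 0.0585), nor did Cd36 (0.10, 0.359), Srebf1 (0.16, 0.135) or Fgf21 (-0.06, 0.82). The non-call of Plin2 was not firm, as it passed in 11 of 45 other settings, with changes from 0.14 to 0.26. The 3 probe sets of Cd36 ran from 0.10 to 0.33.

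Cholesterol synthesis genes were higher as a group (camera adjusted p = 0.000413, and 0.464 with an estimated correlation). Of 20 genes, 9 rose and 2 fell (13 and 2 adjusted over the list alone). Dhcr7 rose by 0.42, Lss by 0.34 and Hsd17b7 by 0.31, while Tm7sf2 fell by 0.34. The list mean was higher in 20 strains. Bile acid genes went both ways, with 5 of 23 higher and 10 lower, the same counts adjusted over the list alone (camera adjusted p = 0.0804). Cyp2c70, which makes muricholic acids, fell by 0.66 and Nr0b2, a repressor of bile acid synthesis, by 0.58, whereas the transporter gene Slco1a4 rose by 0.53 and Cyp8b1 by 0.46. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, did not pass (0.26, adjusted p = 0.143).

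Enzymes that use vitamin B6 or handle it were higher as a group, a list of interest because isoniazid binds the vitamin. Of 21 genes, 9 rose and 1 fell, or 11 and 2 adjusted over the list alone (camera adjusted p = 0.000413, and 0.204 with an estimated correlation). Agxt2 rose by 0.43 in all 31 strains, Alas1 by 0.80, Got1 by 0.64 and Kynu by 0.34. Among 24 genes of amino acid catabolism and the urea cycle, 10 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.00111, and 0.464 with an estimated correlation). Slc25a15, the mitochondrial ornithine carrier, rose by 0.26, and Prodh, which degrades proline, fell by 0.54. In heme metabolism Alas1 stood apart: 1 of 13 genes rose and 3 fell, Blvrb by 0.23, Abcb6 by 0.15 and Hmox1 by 0.16 (2 and 4 adjusted over the list alone). Fech, the last enzyme of heme synthesis, did not pass (-0.07, adjusted p = 0.0722).

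Targets of the drug receptors CAR and PXR were higher as a group, with 7 of 17 rising and 0 falling (8 and 0 adjusted over the list alone). The list had a camera adjusted p of 0.00579, and of 0.204 with an estimated correlation. Aldh1a7 rose by 0.59 in 30 strains and Cyp2b10 by 0.87, followed by Cyp2c55 (0.23) and Cyp2b9 (0.19). Among genes of isoniazid metabolism, the acetyltransferase genes Nat2 (0.18) and Nat1 (0.20) rose, while the carboxylesterase gene Ces1d (-0.51) and Gsta3 (-0.28) fell. Cyp2e1 fell by 0.06 (adjusted p = 0.0256), and was lower in 26 strains, but lost its call in 3 of 45 other settings (highest adjusted p 0.0971). Among targets of the oxidative stress factor NRF2, 3 of 19 rose and 8 fell, or 4 and 9 adjusted over the list alone (camera adjusted p = 0.0501). Gclc (-0.34) and Gclm (-0.19), the subunits of the enzyme that starts glutathione synthesis, and Osgin1 (-0.57) and Abcc4 (-0.37) fell. Of the genes of the integrated stress response, 4 of 24 rose and 8 fell, also adjusted over the list alone (0.0501), Chac1 by -0.47 and Vldlr by -0.37.

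Genes of oxidative phosphorylation were slightly higher, with 23 of 30 rising and 1 falling, also adjusted over the list alone. Their mean was 0.09 ± 0.07 (SD over 31 strains) and was above 0 in 26 strains (camera adjusted p = 1.52e-12, and 0.204 with an estimated correlation). Atp5o rose by 0.19, Sdhb by 0.19, Cox7a2 by 0.17 and Cox5b by 0.16. In the unfolded protein response, which raises folding capacity in the endoplasmic reticulum, 9 of 20 genes rose and 1 fell, or 11 and 1 adjusted over the list alone (adjusted p = 0.000413, and 0.464 with an estimated correlation). Sec61b rose by 0.42, Pdia4 by 0.33 and Pdia3 by 0.31, and Herpud1 fell by 0.28. Of 15 genes of gluconeogenesis and fasting, 5 rose and 2 fell, or 6 and 3 adjusted over the list alone (0.0501), with Fbp1 at 0.23 and Pcx at 0.23. The Gapdh control probe sets of the arrays were higher in 30 of 31 strains, by 0.29 ± 0.15 (SD). The 3' minus 5' signal of the pyruvate carboxylase control differed by 0.23 ± 0.20 and was higher in 27 strains. Both had a permutation p of 1e-05, the smallest that the resamples could give. Pcx, the gene of the latter control, itself rose by 0.23, so this difference alone does not show a change in RNA quality. The 3' minus 5' signal of actin differed by 0.00 (permutation p = 0.861), and that of the transferrin receptor by -0.05 (permutation p = 0.0386, adjusted 0.0901), higher in 10 strains and not passing.

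Interferon-induced genes were lower as a group (camera adjusted p = 2.34e-11, and 0.204 with an estimated correlation). Of 21 genes, 0 rose and 16 fell (0 and 17 adjusted over the list alone), and the list mean was -0.32 ± 0.33. Rsad2 fell by 0.78, Iigp1 by 0.44, Mx1 by 0.41 and Mx2 by 0.20. Of 25 acute phase genes, 1 rose and 10 fell, or 1 and 12 adjusted over the list alone (adjusted p = 0.000393, and 0.464 with an estimated correlation). Saa3 fell by 0.61, Mt2 by 0.55, Il1r1 by 0.38 and Itih4 by 0.22. Of 15 targets of p53, 0 rose and 7 fell, also adjusted over the list alone, with Btg2 at -0.45 and Trp53inp1 at -0.42 (0.000272, and 0.204 with an estimated correlation).

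Markers of other liver cells were tested in the same way. Of 16 macrophage markers, 9 fell and 0 rose, or 10 and 0 adjusted over the list alone (camera adjusted p = 0.000396, and 0.464 with an estimated correlation). Cd5l fell by 0.28, Csf1r by 0.28 and Lyz2 by 0.26. Among 14 endothelial markers Stab2 (-0.30) and Kdr (-0.13) fell, 2 also adjusted over the list alone (camera adjusted p = 0.0425, and 0.508 with an estimated correlation). Of the 5 morning genes of the circadian clock, Cry1 fell by 0.23, and 4 fell when adjusted over the list alone (0.0452, and 0.464 with an estimated correlation). In 42 other settings with the preset correlation the endothelial list lost its call in 19 (highest adjusted p 0.131) and the morning clock list in 15 (0.135). The lists of markers of T and NK cells (0.0759), B cells (0.149), stellate cells (0.149), red cells (0.212), bile duct cells (0.25) and neutrophils (0.258) did not pass camera. In that order 1, 2, 1, 1, 2 and 1 of their genes fell, and 1 bile duct gene rose, or 1, 2, 0, 1, 3 and 0 and again 1 adjusted over the list alone. In all, 12 of 37 lists passed camera, 6 higher and 6 lower, 0 did so with an estimated correlation, and 22 passed fry, which tests whether the genes of a list move on balance one way and does not compare them with other genes. The median, mean and test differed in sign for the heme, cell cycle, evening clock and periportal lists. In 6 of 100 relabellings of animals within strains, the real one included, at least 12 lists passed. The relabellings other than the real one had a median of 6 lists passing and a highest of 16. The median estimated correlation over the lists was 0.158, above the preset value. Higher or lower as a group therefore means a call at the preset correlation only, and chance is not excluded for the 12 lists.

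**Figure D1:**
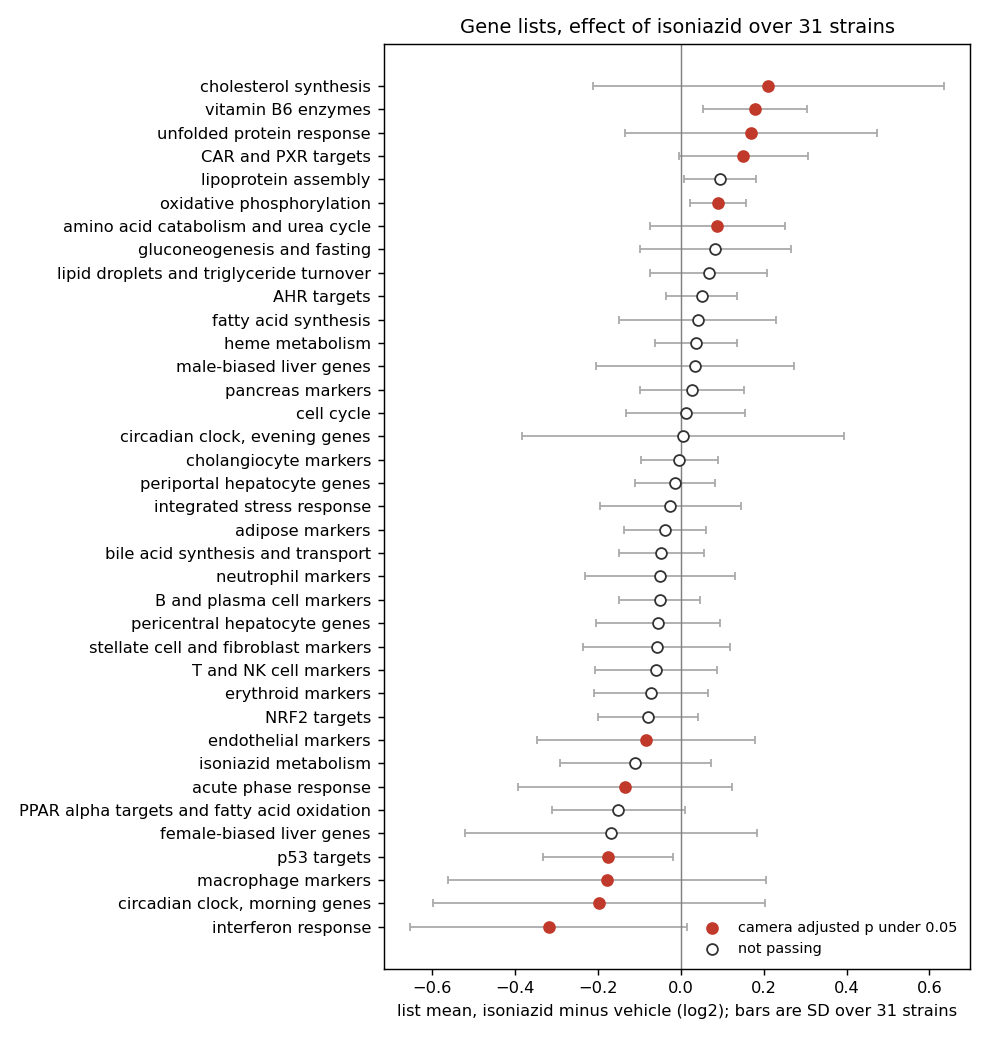
Mean log2 change under isoniazid of each of the 37 gene lists, with bars for the SD over 31 strains, where filled points mark a camera adjusted p under 0.05. Oxidative phosphorylation lies at 0.09 with a short bar, and the interferon list at -0.32 with a long one.

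The next comparisons asked whether strains with steatosis responded in another way. Of the 9 strains with deaths, which had fewer isoniazid arrays, 1 was a steatosis strain. Status was thus partly confounded with deaths. In the 13 steatosis strains 1852 genes changed, 1041 higher and 811 lower. In the 18 strains without it 1503 changed, 754 higher and 749 lower. In both groups 536 genes rose, where independent lists would share 43.3, and 482 fell, where they would share 33.5, with 0 genes in opposite directions. Alas1 rose by 1.04 ± 0.48 (SD) in steatosis strains and by 0.62 ± 0.51 in the others. Apoa4 rose by 1.19 ± 0.76 and 0.73 ± 0.39, and Scd1 changed by -1.84 ± 1.16 and -1.24 ± 0.69. Mean effects in the groups had Pearson r of 0.81 across genes, which are not independent replicates. Of the 3636 genes, 2520 had the larger mean effect in steatosis strains, with a median ratio of 1.23. A measure of response size was added after the data were seen, the mean change over those genes in their common direction. It was 0.22 ± 0.08 (SD, n = 13) in steatosis strains and 0.18 ± 0.06 (n = 18) in the others (permutation p = 0.101, and 0.168 without the narrow-spread arrays). NZW/LacJ had the highest value, 0.39, and RIIIS/J the lowest, 0.08. NOR/LtJ had 0.17 and SEA/GnJ 0.17, or 0.15 and 0.17 without the narrow-spread arrays. Without the narrow-spread arrays 2311 genes changed in the strains without steatosis, and 632 when only strains without deaths were used.

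**Figure D2:**
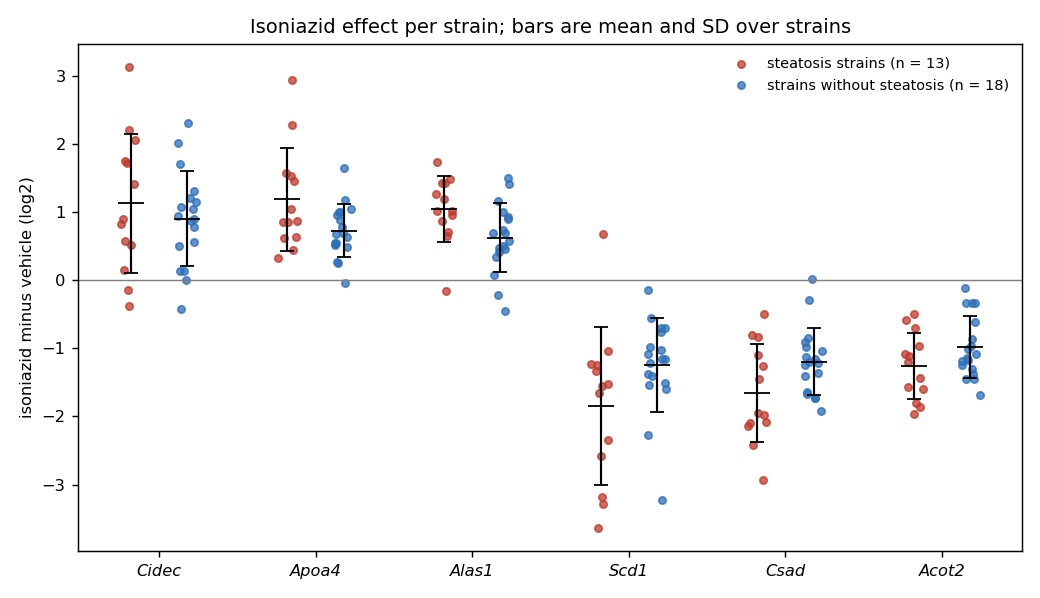
Log2 change under isoniazid of Cidec, Apoa4, Alas1, Scd1, Csad and Acot2, with 1 point per strain by steatosis status and the mean and SD over strains. Acot2 is below 0 in all 31 strains, and the status groups overlap for every gene.

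No gene differed in its isoniazid effect between steatosis strains and the others after adjustment. By limma the count was 0, with 491 genes at an unadjusted p under 0.05 where 907 would be reached by chance, and 35 genes with animals as replicates. The difference was 0.42 for Alas1 (95% interval 0.08 to 0.77), -0.60 for Scd1 (-1.22 to 0.03), 0.23 for Cidec (-0.35 to 0.81), 0.23 for Plin2 (-0.06 to 0.53) and 0.40 for Fgf21 (-0.10 to 0.91). The adjusted p was 1.00 for each. The smallest p-values, none passing, were those of Accsl (-0.18), Gclm (-0.19), Gm9222 (0.28), Fbxo17 (-0.29) and Atp2b2 (0.24). Gclm changed by -0.30 ± 0.16 in steatosis strains and by -0.11 ± 0.08 in the others. The cholesterol synthesis list had a lower effect in steatosis strains, 0.11 against 0.29 (camera adjusted p = 4.3e-05, and 0.836 with an estimated correlation). None of its genes passed, 0 also when adjusted over the list alone, with Mvd at -0.44 and Hmgcs1 at -0.33. In 99 of 100 splits of the strains at least 1 list passed.

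Livers of vehicle animals were compared by status to ask whether the strains differed before treatment. By limma 0 genes passed, with 737 at an unadjusted p under 0.05, and 1957 with animals as replicates, a count reached by 25 of 100 splits of the strains. D3Ertd751e was closest, at -0.33 in steatosis strains (adjusted p = 0.0944), but at 0.01 with the mean of its probe sets (adjusted p = 0.997). Accsl (0.13), Zfhx2os (0.14), Slfn10-ps (-0.19) and Ppt1 (0.44) came next, each with an adjusted p of 0.988. Cd36 lay at -0.65 (95% interval -1.36 to 0.06) and Cidec at -0.60 (-1.36 to 0.16), neither passing. By camera 13 lists passed, 9 higher and 4 lower in steatosis strains, and 0 with an estimated correlation, where the smallest adjusted p was 0.454. In 7 of 100 splits at least 13 lists passed. The interferon list was higher (5.2e-06, and 0.491 with an estimated correlation), and Iigp1 (0.45) and Psmb8 (0.54) were the 2 of 21 genes that passed when adjusted over the list alone. Cholesterol synthesis was higher (0.00059), while lipid droplet genes (0.00059), gluconeogenesis (0.00059) and oxidative phosphorylation (6.7e-06) were lower, with estimated-correlation adjusted p of 0.491, 0.454, 0.454 and 0.491. Markers of B cells (0.01), T and NK cells (0.011) and macrophages (0.049) were higher (0.454, 0.491 and 0.601 with an estimated correlation).

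The 9 strains in which isoniazid animals had died were compared with the other 22, with survivors only. By limma 0 genes differed in effect, with 422 at an unadjusted p under 0.05, and 0 with animals as replicates. The smallest p-values, each with an adjusted p of 1.00, belonged to Foxs1 (0.26), Hsd3b1 (0.57), Tmem71 (-0.37), Cdkl4 (0.30) and Mfap4 (-0.41). Hsd3b1, an enzyme of steroid synthesis, had effects of 0.29 ± 0.25 in the 9 strains and -0.28 ± 0.48 in the others. Endothelial markers had the higher effect in strains with deaths (camera adjusted p = 5e-05) and oxidative phosphorylation the lower (0.0043), each with 0.787 with an estimated correlation and 0 genes passing when adjusted over the list alone. In 96 of 100 splits at least 2 lists passed.

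Within single strains, tested with animals as replicates, responses ranged widely. PWK/PhJ, a wild-derived strain, had 2747 changed genes, NZW/LacJ 2296, DBA/2J 1045, NOR/LtJ 923 and C58/J 893. A/J and PL/J had 0 by limma, with 974 and 1334 genes at an unadjusted p under 0.05. Summed over strains the calls numbered 11226. With animals relabelled at random within strains, the sum had a median of 742 and reached 3587, so part of the calls can be false. The median count per strain was 80. It was 168 in steatosis strains and 49.5 in the others (permutation p = 0.509 for the mean count), or 114 and 106.5 without the narrow-spread arrays and 198 and 29.5 with scan date as a term. It was 9 in the strains with deaths, which have fewer isoniazid arrays, against 115.5 in the rest (11 and 295 without the narrow-spread arrays, 22 and 134 with scan date as a term). Of the 9 strains with deaths 1 was a steatosis strain, so status and the number of isoniazid arrays cannot be fully told apart in these counts. Without the narrow-spread arrays NOR/LtJ had 6 genes and SEA/GnJ 3 instead of 402, while PWK/PhJ had 2945, NZW/LacJ 2443, DBA/2J 1052 and C58/J 1174. Calls without the narrow-spread arrays also rose in strains that had none of them, as in BALB/cJ from 282 to 655. With scan date as a term SEA/GnJ had 22 and NOR/LtJ 1500. The mean change of the 923 genes of NOR/LtJ, in their direction, went from 0.69 (mean SE 0.19) to 0.36 (0.23) without its 2 narrow-spread arrays, and that of the 402 genes of SEA/GnJ from 0.89 (0.24) to 0.57 (0.31) without its 1.

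**Figure D3:**
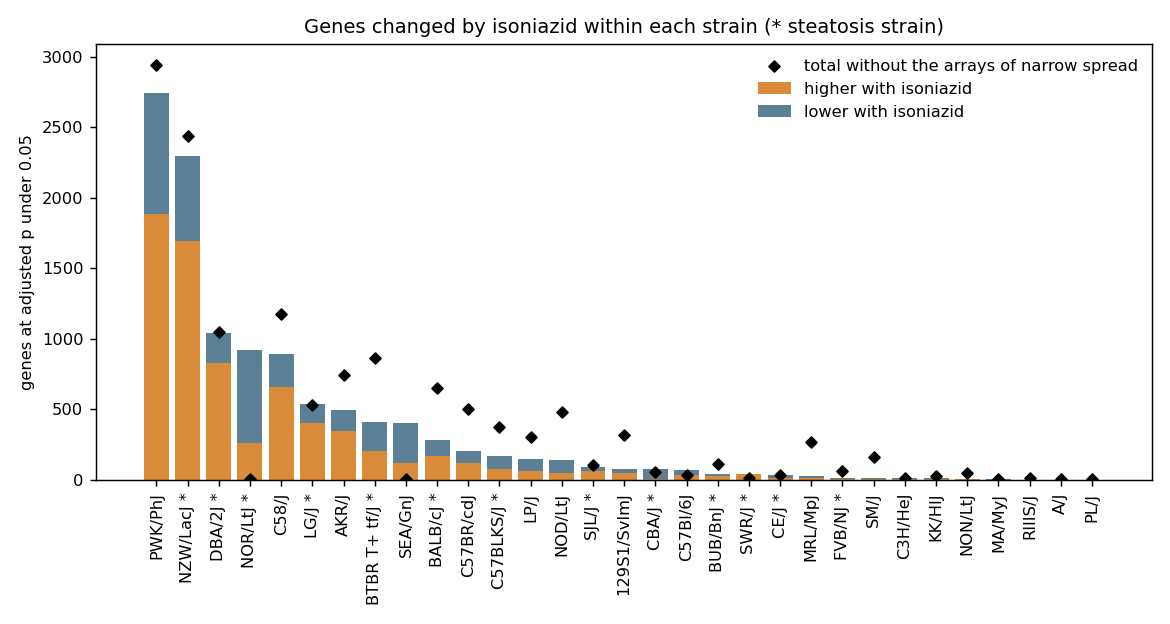
Number of genes changed by isoniazid in each strain at an adjusted p under 0.05, stacked as higher and lower, with diamonds for the total without narrow-spread arrays and stars for steatosis strains. PWK/PhJ reaches 2747 and NZW/LacJ 2296, and NOR/LtJ falls from 923 to 6.

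The effect of isoniazid differed between strains for 3084 genes (17.0%) by the F test of the interaction, and for 1313 to 2194 when 1 animal number was left out (1313 without animal 2). Psmd8, a proteasome subunit gene, had F = 8.20 and rose by 1.39 in PWK/PhJ. Porcn (F = 9.80), which attaches lipid to Wnt proteins, reached 2.73, 2010204K13Rik (8.07) 3.06 and Krtcap2 (7.52) 1.33, all in PWK/PhJ. Slc27a5 (8.35), a bile acid and fatty acid coenzyme A ligase, had its lowest value, -1.17, in NZW/LacJ. Each passed in every setting that had it, but the order by F changed: without PWK/PhJ it was 2.24 for Porcn and 2.80 for 2010204K13Rik, and 3.57 for Slc27a5 without NZW/LacJ. Psmd8 had 4.83 without animal 2 and Krtcap2 4.99 without animal 4, the lowest of each. Of the 3084 genes, 937 (30.4%) deviated most in PWK/PhJ, 561 (18.2%) in NZW/LacJ, 294 (9.53%) in SEA/GnJ, 233 (7.56%) in C58/J and 171 (5.54%) in NOR/LtJ. Without the narrow-spread arrays 3137 genes differed, of which 1067, 547, 95, 299 and 32 deviated most in these strains. Psat1 ranged over 6.08 log2 units, from -2.06 in MA/MyJ to 4.02 in PWK/PhJ. Cyp3a16 ranged over 6.22, from -4.63 in AKR/J to 1.59 in C3H/HeJ.

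Strains also differed from one another without treatment. Among vehicle animals 9684 genes (53.4%) differed by the F test. Serpina1c, an alpha-1-antitrypsin gene, had the largest F, 469, and lay at 14.22 in LG/J and 6.60 in PWK/PhJ. Wfdc21 (F = 307) lay at 13.01 in CBA/J and 5.03 in PWK/PhJ, and Ugt3a2 (F = 307) at 11.05 in LG/J and 2.61 in PWK/PhJ. Nlrp12 (F = 305) ranged from 2.63 in 129S1/SvImJ to 10.82 in C58/J, and Gm7969 (F = 260) from 1.91 in PWK/PhJ to 7.26 in C57BR/cdJ. Without PWK/PhJ the F was 8.66 for Serpina1c, 3.53 for Wfdc21 and 154 for Ugt3a2, each still passing. The lowest over all settings was 206 for Nlrp12 and 152 for Gm7969. The match of these probe sets to the sequence of each strain was not tested.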

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

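The tests of narrow-spread arrays were chosen only after the results were seen; the scan date test of strain counts and the relabelling and splitting of samples were planned before. Each relabelling or splitting drew 100 arrangements, the real one included.

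The SD of the log2 values set 7 arrays apart from the other 3 of their group: 129S1/SvImJ isoniazid animal 2 (2.25), C57BR/cdJ isoniazid animal 1 (2.18), CE/J vehicle animal 3 (2.16), MRL/MpJ isoniazid animal 1 (2.19), NZW/LacJ isoniazid animal 3 (2.28), SJL/J isoniazid animal 2 (2.32) and SWR/J vehicle animal 2 (2.10). Chance sets apart about 1 in 20 groups, so 2.65 of the 53 groups tested. Of the 7 arrays, 4 belong to the 21 of narrow spread.

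Those 21 arrays, from 19 strains and 8 scan dates, deviate from their groups in a shared way, with a median r of 0.68 between strains. Tnik (2.80), Upk3b (2.51) and Robo1 (2.28) are higher on them and Pacrgl (-1.80) is lower. Degraded RNA raises 3' minus 5' signals, and on these arrays they were not higher than in the rest of the group. That of actin differs by -0.0144 (SE 0.0372), that of the transferrin receptor by -0.0623 (SE 0.0480) and that of pyruvate carboxylase by -0.424 (SE 0.0770). A narrower spread of values can itself shrink such differences, so they cannot exclude degraded RNA. The tables argue against a scan date, since the 2 fullest dates hold only 7 of the arrays. They are as frequent among isoniazid as among vehicle arrays (Fisher's exact p = 1, two-sided), which cannot exclude a small effect of treatment. A step of hybridisation or RNA handling that these tables do not record may be the cause, and was not tested.

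The many changed genes of NOR/LtJ and SEA/GnJ may rest on these arrays: without all 21 of them 6 and 3 genes were called, of 923 and 402, and without only the 2 and 1 of the strain 4 and 2, but 7673 and 4532 when its other 2 and 1 isoniazid arrays were left out instead. Fewer arrays also lose calls in NOR/LtJ, with 100 to 269 when 1 of each kind was left out. SEA/GnJ is left with 1 isoniazid array, assumed to vary like other groups, and scan date also stays open there, with 22 genes as against 1500 in NOR/LtJ with scan date as a term. In PWK/PhJ, NZW/LacJ, DBA/2J and C58/J 2945, 2443, 1052 and 1174 genes were called without the narrow-spread arrays, of which 2249, 1993, 694 and 751 are shared. All strains share 1 estimate of the spread, and calls also rose in strains without such an array, as in BALB/cJ from 282 to 655. The counts therefore cannot exclude a part of these arrays. The response size in these strains was 0.30, 0.39, 0.33 and 0.20 in that order, and 0.28, 0.39, 0.33 and 0.21 without the narrow-spread arrays. The tables argue against scan date, with 2432, 2465, 1134 and 862 genes called with it as a term, of which 2287, 2175, 951 and 762 are shared. A larger response of PWK/PhJ, NZW/LacJ and DBA/2J stays open as a hypothesis. In C58/J the response size of 0.20 was near the mean of 0.18 ± 0.06 (SD) in strains without steatosis. It does not show a larger shared response there. Other differences between cages or batches that the labels do not give stay open in each of these strains. In PWK/PhJ a spread between animals above the shared estimate also stays open, since its isoniazid arrays were less alike than most.

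Relabelling argues against chance for the effect over 31 strains. Only the real one of 100 arrangements gave as many genes (3636, the highest other 7). The same holds in steatosis strains (1852, highest other 308) and in the others (1503, highest other 2). It also holds for the sum within strains (11226, highest other 3587, median of the others 742). Strain differences among vehicle animals gave 9684, with 1574 as the highest other. With 100 arrangements no share below 1 in 100 can be shown. For the interaction 1 of 100 relabellings gave as many genes (3084, highest other 351). Relabelling within strains also removes the effect that strains share, so it cannot exclude chance for differences between strains in that effect. Chance is not excluded for the 12 lists that passed over strains, since 6 relabellings gave as many and the highest other gave 16. The median of the others was 6 lists.

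For the comparisons between strain groups chance is not excluded. Where the real count is 0, as for the difference by steatosis (highest other 1535), vehicle levels (highest other 1) and deaths (highest other 14), all 100 splits reach it by construction, which says nothing about chance. With animals as replicates, 21 splits gave at least 35 genes for the difference (highest other 4286, in a fit that leaves out the spread between strains, whose effects differ for 3084 genes) and 25 at least 1957 for vehicle levels (highest other 3328, median of the others 1542). For gene lists, 99 splits reached the real 1 by steatosis (highest other 14), 7 reached 13 in vehicle animals (highest other 16) and 96 reached 2 by deaths (highest other 14).

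The isoniazid effect differs between strains, by the F test of the interaction, for Porcn (F = 9.80), Slc27a5 (8.35), Psmd8 (8.20), 2010204K13Rik (8.07) and Krtcap2 (7.52). It also differs for 22 of the 24 genes named over 31 strains. Among probe sets without a single gene name, which no comparison used, 468 of 9944 change over 31 strains, 207 higher and 261 lower.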

How the results depend on the processing

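Leaving out the narrow-spread arrays, and applying median centring, mean probe sets, the filter on dim genes, strains without deaths and left-out animal numbers to gene lists, were chosen after seeing the data. All 24 genes named over 31 strains kept their call and sign in every setting that had them, which for Serpina4-ps1 leaves out the filter on dim genes. Of the 12 lists, 10 kept their call in all 42 camera settings with the preset correlation, the exceptions being the endothelial and morning clock lists. With an estimated correlation 0 of the 12 lists passed. Among the fixed genes that did not pass over 31 strains, Plin2 passed in 11 of 45 other settings, Fech in 7, Cyp7a1 in 2, and Cd36 and Srebf1 in 1 each. Cyp2e1 lost its call in 3 and Fasn in 1. Fasn reversed within scan date 9 (-0.0504), and the cause was not tested.

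With a 1.5-fold change as a second threshold, which is stricter by construction, the counts were 54 over 31 strains, 98 in steatosis strains, 34 in the others and 6750 within strains. With animals as replicates, which leaves out the spread between strains, they were 3605 and 2994 in the status groups, 35 for their difference and 1957 for vehicle levels. Strains without steatosis gave 632 genes in strains without deaths only, where fewer strains are tested, and 2311 without narrow-spread arrays. The estimated correlation gave 0 lists in each comparison, and fry 22 over 31 strains and 0 by steatosis, in vehicle animals and by deaths. Lists by steatosis numbered 5 with scan date as a term and 2 without dim genes. Lists by deaths numbered 5 with mean probe sets, 5 without dim genes and 5 without narrow-spread arrays. The cause of the changes in lists was not tested.

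Leaving out 1 animal number, or 1 strain, gave 2851 to 3160 or 3366 to 3787 genes over 31 strains, 1418 to 1723 or 1342 to 2098 in steatosis strains, and 995 to 1246 or 1185 to 1622 in the others. It gave 0 to 0 for the difference and for deaths, and 0 to 1 for vehicle levels (1 without animal 3, AKR/J or SM/J). Within strains it gave 7793 to 11064 or 8731 to 11801, for the interaction 1313 to 2194 or 2334 to 3277, and for vehicle strain differences 8111 to 8831 or 9306 to 9788. Lists numbered 11 to 15 or 10 to 17 over strains, 0 to 7 or 1 to 5 by steatosis, 9 to 14 or 10 to 15 in vehicle animals, and 2 to 9 or 2 to 7 by deaths. Some strains then keep 1 isoniazid array, which is assumed to vary like other groups. The interaction had 1699, 1313 and 1692 genes without animals 1, 2 and 4, and strains without steatosis 995 without animal 4.

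Animal numbers do not pair the samples, since 23 of 111 same-numbered pairs had r over 0.1 (mean r -0.0154) and 24 isoniazid arrays correlated best with their own number, against 27.75 by chance. With the number as a block the counts were 3623, 1847 and 1513 over all, steatosis and other strains, 0 for the difference, vehicle levels and deaths, 11161 within strains, 3064 for the interaction and 9683 for vehicle strain differences. The block gave 12 lists over strains, 2 by steatosis, 13 in vehicle animals and 4 by deaths. Array signals near background limit what low genes can show.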

Other observations

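The proteasome list was chosen only after Psmd8 was seen among the genes that differ most between strains, and its tests in PWK/PhJ and NZW/LacJ were set before their results were seen.

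Genes of the proteasome, the complex that degrades ubiquitin-marked proteins, are higher under isoniazid. Over 31 strains the mean of 33 subunit genes, without Psmd8, is 0.17 ± 0.19 log2 units (SD), above 0 in 25 strains (sign-flip permutation p = 1e-05, the smallest the resamples could give). Of the 33 genes, 30 rise and 0 fall, with Psmd14 at 0.34 and Psmc4 at 0.33, chosen after their values were seen. The mean is 0.68 in NZW/LacJ, where 30 subunits pass, 0.47 in DBA/2J (24), 0.41 in LG/J (14), 0.39 in C57BR/cdJ (13), 0.36 in SJL/J (7) and 0.36 in PWK/PhJ (17). An exact permutation p of 0.0286, the smallest that 4 vehicle animals against 4 or 3 isoniazid animals allow, was reached in 13 strains (adjusted 0.0681), so the test can pass in a strain only if more strains reach this p.

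A coordinated rise of proteasome genes in PWK/PhJ and NZW/LacJ may be a biological response, a hypothesis found and tested on the same data. Against an origin in narrow-spread arrays, the mean stays at 0.30 in PWK/PhJ and 0.63 in NZW/LacJ without them. Against a shift of all genes of similar level, the median lies at percentile 99.95 in PWK/PhJ and 100 in NZW/LacJ among random lists of genes matched by level. Genes of the random lists were drawn singly, so the percentiles do not show how rare such a rise is among lists of genes that move together. Other technical differences between the animals of these strains were not tested.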
